A study of Danio rerio with 6 samples.

How the data were processed

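RNA was sequenced from whole zebrafish (Danio rerio) embryos at 72 hours post fertilization. The labels put 3 samples in a wild type group and 3 in a group of rhpn2 mutants, each lettered a to c. RNA was extracted with TRIzol and libraries were made with the NEBNext Ultra RNA kit for Illumina, per the labels' protocols. That kit's name has no directional mark, and whether counting used strand is not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. The labels name no shared clutch, collection day, time of day or separate parents. The p-values therefore measure the spread between these samples, which may be partly technical.

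The authors deposited 1 table of 31624 genes with Ensembl gene identifiers, read counts and FPKM values for each sample, exonic gene sizes, coordinates, symbols and Gene Ontology terms. The deposited counts are whole numbers with a different total in each sample, and no normalization was applied to them. The deposited FPKM values equal the count divided by the exonic gene size and by the sample's own total count, as recomputed from the table (ratio of the implied total to the count total 1 in each sample). The tools named in the submitters' processing notes are bcl2fastq 2.20.0.422, fastp 0.23.2, STAR 2.7.10a and Salmon 1.9.0, with no role for any of them. Which tool made the counts and which genome build and annotation release were used are not given in the sources used here. Coordinates are those of the deposited table, whose highest position on chromosome 4 is 76624966, and no build is assigned to them. Of the 31624 identifiers, 26154 were in the gene name table used to match the symbols of the lists. Among all 31624 genes, 5268 had no count in any sample.

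Total counts were 15203791, 14918069 and 15258723 in wild type a, b and c and 17056923, 16368167 and 15013932 in mutant a, b and c. A count of 3, the floor used for a gene with no count, equals 0.176 to 0.201 CPM in a single library. This floor and the intervals of count ratios cover counting error only, since reads amplified without molecular identifiers are not independent molecules, whereas the interval of the rhpn2 level was taken from its SE, which includes the spread between samples. Pairs of libraries of the same group differed by a chi-square per degree of freedom of 4.196 to 14.48 over genes with a mean count of at least 10, far above sampling noise, so each library was counted as its own sample.

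Because the table holds counts, genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts. The plan for the genes that changed foresaw this, while the plans for the genes higher, the genes lower and rhpn2 itself named limma, which is given as an alternative. Genes passed filterByExpr (minimum count of 10 and minimum total count of 15), libraries were scaled by TMM factors, and group was the only term. Benjamini-Hochberg adjustment ran over 20032 genes with a threshold of 0.05. Standard errors (SE) of log2 changes were taken as the change divided by the square root of the quasi-likelihood F.

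Before the data were examined, 36 gene lists were fixed for tissues, signalling, the ear, stress and metabolism, 1 of which is not reported here. Of 853 symbols, 824 were found. The 947 tested members belonged to 1 list each. Lists with at least 5 members were tested with camera in limma 3.58.1 on log2(FPKM + 1) over 17737 genes with a mean FPKM of at least 1, at a preset correlation of 0.01, and also with an estimated correlation and with fry. Members below that mean were left out of these tests but not of the counts of members. For example, camera used 16 of 30 hair cell, 25 of 31 motile cilia, 17 of 21 intestine and 31 of 35 photoreceptor genes. The named genes are rhpn2, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, with a mean FPKM of at least 2 in the higher group and no clone-based symbol, and the 4 members with the smallest p in each list that passed and in the hair cell and otic lists. Members named beyond this rule were chosen after their values were seen.

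The steps were tested on simulated counts made from these libraries for the comparison of mutant with wild type over 20032 genes. edgeR recovered 48.0% of genes changed 1.5-fold, 80.0% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, with 50 genes per size, and called 12 of 19832 unchanged genes. camera called a list of genes lowered 1.5-fold and none of 100 random lists. Genes were simulated independently of each other, so this cannot show how camera behaves where members of a list move together. The simulation changed few genes, with as many rises as falls, whereas 33.2% of genes were called in the data. It therefore did not test the scaling between libraries, and the shares recovered may differ in the data. Alternatives covered the pseudocount, low-count filters, scaling, quantile normalization, the replicate letter as a block, array weights, robust fits, limma, DESeq2 1.42.0 and leaving out each library. Scaling by library totals, camera on the counts and the pairing of limma with other settings were added after seeing the data. Gene Ontology terms with 10 to 300 members were tested with a one-sided hypergeometric test against 8949 tested genes that carry such a term. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.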

Results

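The transcriptome of whole zebrafish embryos was measured by RNA-seq at 72 hours post fertilization in 3 wild type samples and 3 samples of rhpn2 mutants. The comparison asks how loss of rhpn2, which encodes rhophilin-2, changes gene expression. Libraries held 14918069 to 17056923 counts, and 23729 to 24014 genes had at least 1 count in a sample. The first principal component of log CPM held 67.5% of the variance and separated the groups, while the second held 12.3% and set wild type a apart from the other samples. The 50 most abundant genes took 21.9% to 23.62% of the counts in wild type libraries and 19.29% to 20.66% in mutant libraries.

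Expression of rhpn2 was lower in every mutant sample. The gene (ENSDARG00000014577, chromosome 7, 38078407 to 38122163 on the plus strand) overlaps si:ch211-134o20.2 on the minus strand. Wild type a, b and c had 685, 755 and 743 counts, and mutant a, b and c had 195, 194 and 188. FPKM was 11.5 ± 0.676 (SD, n = 3) in wild type and 2.85 ± 0.131 (SD, n = 3) in mutants. The mutant level was 23.0% of wild type (95% interval 19.7% to 26.9%), a log2 change of -2.12 with an SE of 0.10 and an adjusted p of 5.04e-08 by the quasi-likelihood test of edgeR. An exact two-sided permutation test of log2(FPKM + 1) gave p = 0.1, the smallest value that 3 samples against 3 allow.

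**Figure D1:**
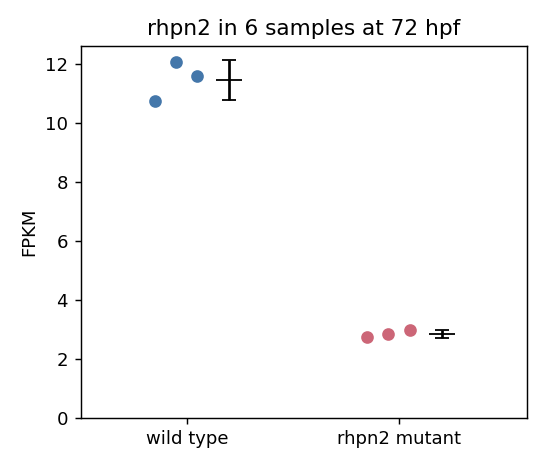
FPKM of rhpn2 (y axis) in each of 3 wild type and 3 mutant samples (points), with the group mean and SD (bars). The mutant samples lie between 2.73 and 2.99 and the wild type samples between 10.75 and 12.08.

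Of 20032 genes tested, 6654 (33.2%) changed at an adjusted p below 0.05, 3307 of them higher and 3347 lower in mutants. An absolute log2 change of at least 1 was reached by 1591 genes, 637 higher and 954 lower. The groups did not overlap for 47.8% of genes, where chance gives 10%. The share of called genes that were higher, 49.7% with TMM scaling, depended on scaling. In edgeR it was 49.2% with median-of-ratios scaling, 65.0% with library totals and 61.0% when the 50 most abundant genes were left out of the totals. With limma on 17737 genes it was 66.0% on FPKM, which is scaled by library totals, 64.7% with array weights and 50.9% after quantile normalization. Library totals moved the median log2 change of all genes from 0.006 to 0.113, so the log2 changes and counts of members below are relative to the TMM scale unless another is named. The camera and fry tests used FPKM, which is scaled by library totals. Of these, camera compares a list with the other genes, while fry tests it against no change. Without wild type a, 6710 genes changed.

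The largest rises included globins, an actin and a collagen chaperone. ACTC1 (1 of many), a copy of the gene for cardiac actin, rose 104-fold from 0.587 ± 0.166 to 66.4 ± 4.29 FPKM (SD, n = 3 each), a log2 change of 6.70 with an SE of 0.17 and an adjusted p of 1.79e-10. Of the globins, hbbe3 rose 68.3-fold from 2.93 ± 1.13 to 216 ± 48.4 FPKM, and hbae1 rose 9.72-fold. The gene serpinh1b, whose product is a collagen chaperone of the endoplasmic reticulum, rose 14.9-fold from 3.92 ± 0.256 to 63.0 ± 4.46 FPKM. The remaining rises were CYP27A1 (1 of many), a sterol hydroxylase copy (15.3-fold), mal (13.6-fold, and 27.4-fold without wild type a), the galectin gene lgals1l1 (8.44-fold), the DNA repair gene fancf (7.18-fold), enox1 (4.62-fold) and ppef1 (4.58-fold). By the rule that picked them, each was higher in all 3 mutant samples than in any wild type sample. Reads of CYP27A1 (1 of many), hbae1, lgals1l1 and ACTC1 (1 of many) may be shared with overlapping genes or near-identical copies, so their values are uncertain.

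Of the 10 largest falls, 3 were in genes of pancreatic proteases. The genes ctrb1, CELA1 (1 of many) and ctrl fell 21.5-fold, 13.5-fold and 10.6-fold. The bile acid binding protein gene fabp6 fell about 20.6-fold and the chitinase gene chia.2 fell 11.5-fold. For ctrb1 the values were 23.9 ± 11.7 FPKM in wild type and 1.18 ± 0.638 in mutants (SD, n = 3 each), a log2 change of -4.43 with an SE of 0.43 and an adjusted p of 1.5e-05. This gene lies on chromosome 7 within 10 Mb of rhpn2 (start 34804496), and its neighbour zgc:112160 also fell (log2 change -3.39). Whether a haplotype linked to rhpn2 contributes to the fall of ctrb1 was not tested. The fetuin gene ahsg1, whose product is secreted by liver, fell 17.1-fold, pm20d1.1 fell 13.8-fold, the lectin gene hbl3 fell about 35.8-fold and guca1c, a guanylate cyclase activator of cones, fell about 23.7-fold. The mutant samples together held only 4 counts of fabp6, 7 of hbl3 and 10 of guca1c, so the sizes of these falls rest on few reads. Without mutant c the ratio of wild type to mutant counts for fabp6, scaled by library size, was 63.4 (95% exact binomial interval 11.1 to 2530, 1 mutant count left), and without mutant a it was 84.5 for hbl3 (23.1 to 702, 2 left), while guca1c then fell 36.7-fold. The small nucleolar RNA snoU2_19 had 68 counts in wild type and 0 in mutants, at least 26.1-fold lower with a floor of 3 counts over the group. CELA1 (1 of many) overlaps another copy, so its value is uncertain.

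Of 33 lists described here that were long enough for camera, 16 passed at the preset correlation, 3 higher and 13 lower in mutants, with p adjusted over 34 lists. Over all 20032 genes tested, 3307 were higher and 3347 lower, the share to set beside the counts of members below. With an estimated correlation 0 lists passed camera after adjustment, 4 lists had an unadjusted p below 0.05, and the lowest adjusted p was 0.373. fry called 15 of these lists moving 1 way on balance, 12 of them among those of camera, and 30 as changed in either direction. On the FPKM scale that fry used, the median log2 change of all genes was 0.101, which favours upward calls and works against downward ones.

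**Figure D2:**
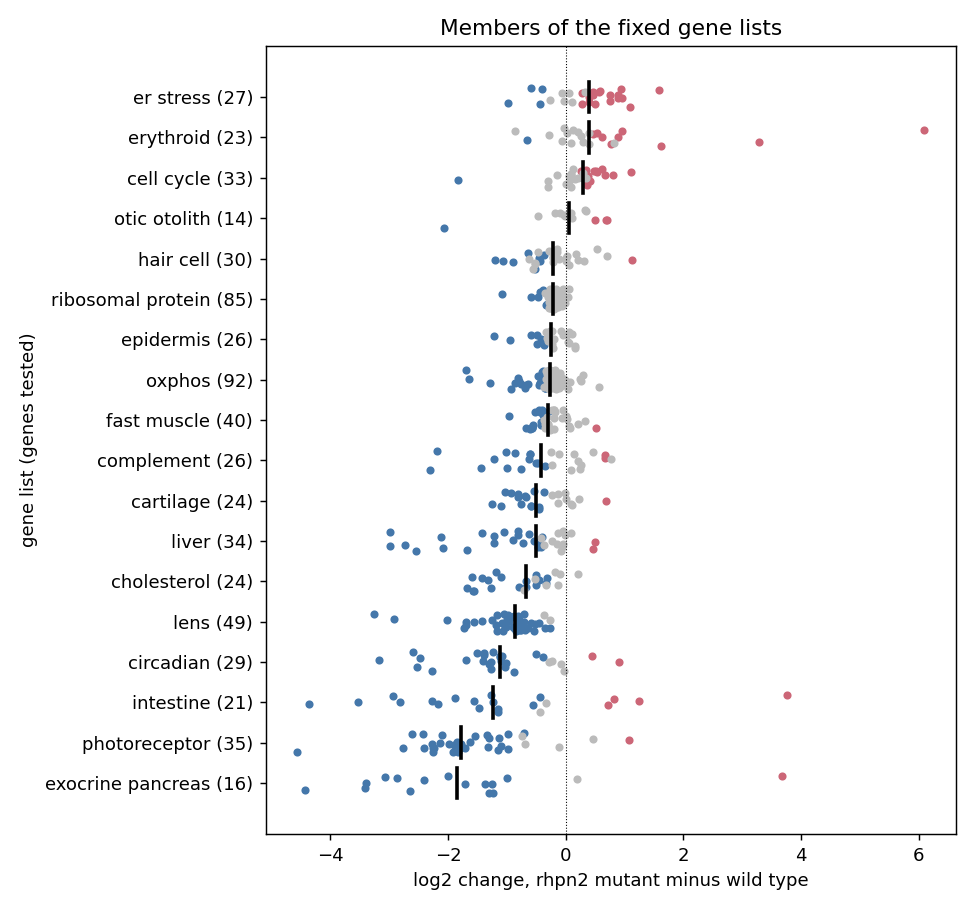
Log2 change (x axis, mutant minus wild type) of each tested member (points) of the 16 lists that passed camera and of the hair cell and otic lists (rows, with the number tested), with the list median as a black bar. Red points rose, blue points fell and grey points did not pass. The exocrine pancreas, photoreceptor and intestine medians are the lowest, at -1.86, -1.78 and -1.24, and the ribosomal protein median, -0.22 here, turns positive with quantile normalization.

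Genes of the eye were lower in mutants. Of 35 photoreceptor genes 30 fell and 1 rose, with a median log2 change of -1.78 (camera adjusted p 2.38e-19, adjusted p = 0.377 with an estimated correlation). They included the ultraviolet cone opsin opn1sw1 (-2.61), the red cone opsin opn1lw2 (-1.92), rcvrn3 (-2.77) and rbp4l (-2.11), while nr2e3, a transcription factor of photoreceptors, rose by 1.08 on the log2 scale. Of 49 lens genes 47 fell and none rose, with a median of -0.87 (camera adjusted p 7.39e-27, adjusted p = 0.373 with an estimated correlation). The crystallin genes crygm2d15, crygm2d11, crygm2d4 and crygm2d17 fell by 3.25, 2.02, 1.74 and 1.69 on the log2 scale, with reads that near-identical copies may share. With p adjusted over the list alone, 30 photoreceptor and 48 lens genes fell.

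Digestive organs followed the same direction. Of 16 exocrine pancreas genes 14 fell, median -1.86 (camera adjusted p 1.85e-08, adjusted p = 0.377 with an estimated correlation), including ctrb1, ctrl, try (-2.01) and prss59.2 (-2.87). Of 34 liver genes 21 fell and 2 rose, median -0.51 (camera adjusted p 7.56e-09, adjusted p = 0.377 with an estimated correlation). Falls in the liver list included haptoglobin gene hp (-2.73), hepcidin gene hamp (-2.99), itih3a (-1.22) and kng1 (-1.23), and the rises were apoba, whose call was lost without mutant b or c (adjusted p 0.0594 and 0.0842), and apoeb, whose call was lost without wild type b or c or mutant b or c (0.0717 to 0.19). Of 21 intestine genes 15 fell and 4 rose, median -1.24 (camera adjusted p 0.000526, adjusted p = 0.377 with an estimated correlation). The villin gene vil1, cldn15la and chia.2 fell by 2.27, 1.27 and 3.52 on the log2 scale, and mal rose by 3.77 (4.78 without wild type a). The other risers were fabp1b.1, pck1 and apoa4b.2, and among genes with a mean FPKM of at least 5 the intestine list had an adjusted p of 0.0862. With quantile normalization the intestine median was -0.62, with 11 falls. Those values came from limma on log2(FPKM + 1) of 17 intestine genes. They therefore differ from the values above in test, pseudocount and genes as well as in scaling. Complement genes, many of them made by liver, fell in 14 of 26 cases and rose in 2, masp1 and c3b.2, median -0.41 (camera adjusted p 0.000665, adjusted p = 0.377 with an estimated correlation). Among them cfhl2, c9, c3a.3 and masp2 fell by 2.18, 1.01, 1.44 and 1.22. The span of cfhl2 overlaps those of cfh and cfhl1, and that of c3a.3 overlaps c3a.2, so their reads may be shared. Adjusted over the list alone, 14 exocrine pancreas, 22 liver, 16 intestine and 15 complement genes fell.

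Sterol synthesis genes fell in 17 of 24 cases and none rose, median -0.68 (camera adjusted p 1.63e-09, adjusted p = 0.373 with an estimated correlation). The sterol sensor gene insig1, the receptor gene ldlra, idi1 and msmo1 fell by 1.57, 1.55, 1.27 and 1.59 on the log2 scale. Of these, insig1 lies on chromosome 7 within 10 Mb of rhpn2 (start 40728393), and the part of a linked haplotype in its fall was not tested. Cartilage matrix genes fell in 15 of 24 cases, median -0.50 (camera adjusted p 1.48e-05, adjusted p = 0.377 with an estimated correlation), among them mia (2.38-fold), matn1 (2.15-fold), epyc (1.75-fold) and col9a2 (1.76-fold), while sox9a, a regulator of chondrocyte fate, rose. Counts adjusted over the list alone were 18 sterol and 15 cartilage genes that fell.

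Genes of the circadian clock were lower in mutants. Of 29 members 23 fell and 2 rose, cry1ba and arntl2, with a median log2 change of -1.12 (camera adjusted p 2.43e-14, adjusted p = 0.373 with an estimated correlation). The light-responsive genes per2 and cry1aa fell 5.56-fold and 4.84-fold, per1b fell 6.07-fold and nr1d1 fell 9.05-fold. For per2, FPKM was 21.1 ± 3.08 in wild type and 4.08 ± 0.448 in mutants (SD, n = 3 each), with an adjusted p of 2.94e-08 by edgeR. When adjusted over the list alone, 24 members fell. The labels give no time of day for either group.

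**Figure D3:**
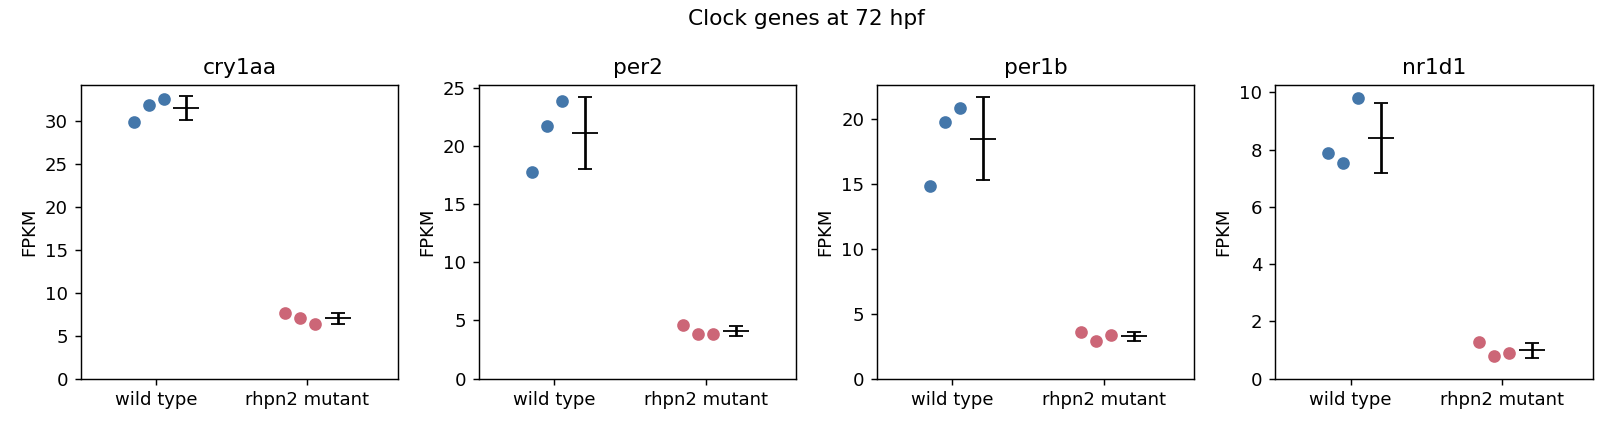
FPKM (y axis, from 0) of cry1aa, per2, per1b and nr1d1 in 3 wild type and 3 mutant samples (points), with the group mean and SD (bars). All 3 mutant values lie below all 3 wild type values for each gene.

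Higher lists covered endoplasmic reticulum chaperones, red blood cells and cell division. Of 27 genes of the unfolded protein and amino acid stress responses, 17 rose and 4 fell, median 0.40 (camera adjusted p 0.000357, adjusted p = 0.373 with an estimated correlation). The rises were led by chaperone genes hspa5 (3-fold), hsp90b1 (2.14-fold), pdia4 (1.93-fold) and calr (1.68-fold), whereas the falls were the stress-induced regulators atf3, ppp1r15a, atf4b and ddit3, the last with an adjusted p of 0.108 without mutant b and 0.0918 without mutant c. Of 23 erythroid genes 9 rose, median 0.39 (camera adjusted p 0.00237, adjusted p = 0.377 with an estimated correlation), with hbbe3, hbae1, the anion exchanger gene slc4a1a (1.62) and the heme synthesis gene alas2 (0.96). The globin hbbe2 fell. The span of alas2 overlaps ela2l on the other strand. Of 33 cell cycle genes 15 rose, median 0.30 (camera adjusted p 0.000231, adjusted p = 0.377 with an estimated correlation), including the mitotic genes mki67 (0.80), cenpe (0.68) and bub1 (0.62). Both copies of rrm2 passed in opposite directions, at -1.82 and 1.11. Adjusted over the list alone, 18 stress, 9 erythroid and 18 cell cycle genes rose.

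Smaller shifts appeared in muscle, skin, ribosomal and respiratory chain genes. Of 40 fast muscle genes 16 fell and myod1 rose (adjusted p 0.0553 to 0.0887 without wild type c or mutant b or c), median -0.30 (camera adjusted p 8.94e-05, adjusted p = 0.443 with an estimated correlation), with the parvalbumin gene pvalb4 at -0.67, casq1a at -0.58 and eno3 at -0.53. Of the 2 genes with the symbol myhz1.1, the one on chromosome 22 (5.39 FPKM in wild type) fell by 0.96 on the log2 scale, while the one on chromosome 5 (1367 FPKM) had a log2 change of -0.36 and did not pass (adjusted p 0.0642). Of 26 epidermis genes 8 fell, median -0.25 (camera adjusted p 0.00533, adjusted p = 0.583 with an estimated correlation), led by krt92 (-1.22), cyt1 (-0.94), ppl (-0.48) and anxa1b (-0.59), and without mutant a the adjusted p was 0.14. The spans of krt92 and cyt1 overlap, so their reads may be shared. Of 92 nuclear genes for the respiratory chain 34 fell, median -0.27 (camera adjusted p 5.14e-08, adjusted p = 0.583 with an estimated correlation), among them ndufs8a (-0.77), cox8b (-1.65), ndufa4 (-0.85) and ndufv1 (-0.67). Of 85 ribosomal protein genes 9 fell, median -0.22 (camera adjusted p 3.58e-05, adjusted p = 0.737 with an estimated correlation), with rpl31 at -1.09, rpl7l1 at -0.47, rpl6 at -0.43 and rpl30 at -0.38. That share of falls is below the 3347 of 20032 over all genes tested. The ribosomal direction reversed with quantile normalization (median 0.02, adjusted p 0.85), its adjusted p was 0.061 without wild type a, and rpl30 lost its call without mutant a (adjusted p 0.102) or mutant b (0.0887) and with limma on FPKM (0.0524 to 0.0853 over its settings other than quantile normalization). Quantile normalization also ended the calls of rpl6 (adjusted p 0.0763), rpl30 (0.117) and the muscle (0.119) and epidermis (0.277) lists, and fry called none of these 4 lists. With library totals the muscle, epidermis, respiratory chain and ribosomal medians were -0.192, -0.145, -0.155 and -0.108, with 14, 6, 23 and 5 falls and 3, 1, 0 and 0 rises. With quantile normalization the first 3 medians were -0.118, -0.114 and -0.085, and the 4 lists had 12, 8, 25 and 4 falls and 4, 3, 0 and 2 rises. Adjusted over the list alone, 20 muscle, 8 epidermis, 35 respiratory chain and 2 ribosomal genes fell.

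Lists for the ear did not pass camera. Of 30 hair cell genes 8 fell and 1, gfi1b, rose, median -0.21 (camera adjusted p 0.159 on 16 of them), with ush1c at -1.06, otofb at -0.46, s100t at -0.52 and tmc2b at -1.21. Of 14 otic genes, coch fell by 2.07 on the log2 scale and hmx3a, oc90 and hmx2 rose by 0.70, 0.69 and 0.50 (median 0.06, mean -0.01, camera adjusted p 0.813). The span of hmx2 lies within that of hmx3a, so their rises may share reads. With library totals the hair cell and otic medians were -0.11 and 0.16, and hair cell falls numbered 6. Limma on quantile-normalized values covered the 16 hair cell genes with a mean FPKM of at least 1, of which 5 fell. Of the 8 falls above, tmc2b, cabp2b and myo15aa lie below that mean, so this count does not show an effect of scaling. Adjusted over the list alone, 1 hair cell gene rose and 8 fell, and 3 otic genes rose and 1 fell. The call of otofb was lost with limma (adjusted p 0.0592 to 0.0616 over 3 pseudocounts), and those of oc90 and hmx2 with DESeq2 (0.0558 and 0.0633). Calls lost without a library were those of oc90 without wild type a or b or mutant b or c (adjusted p 0.0821, 0.0589, 0.0792 and 0.102) and of hmx2 without any library but wild type c (0.0648 to 0.159).

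Other lists described here also missed the threshold of camera. Of 31 motile cilia genes 11 rose, hydin and foxj1a (adjusted p 0.0509 without mutant b) among them, and 1, tekt2, fell (adjusted p 0.397, and 0.0489 with no filter on low values). Of 21 pigment genes 7 rose and gpnmb fell (adjusted p 0.0721, and 0.0225 with no filter on low values, 0.0231 without wild type b and 0.00867 without mutant a). Of 27 neuron genes 6 rose, including tubb5 and elavl3, and nefla fell (adjusted p 0.204, and 0.0316 without wild type c). Of 20 p53 and apoptosis genes 9 fell and sesn2 rose (adjusted p 0.196 for the list, and 0.065 and 0.0818 for sesn2 without wild type b or mutant c), while 4 fell and 3 rose with library totals. Of 19 heat shock genes 5 rose and 4 fell (adjusted p 0.845). For heat shock the median was -0.08 (0.03 with library totals) while the mean, 0.17, and camera pointed up, and for glia, with 4 rises and 6 falls of 17, the median was 0.03 (0.14 with library totals) while the mean, -0.04, and camera pointed down. The heat shock list holds serpinh1b, whose rise of 3.90 on the log2 scale lifts the mean of that list. No gene of 9 in the interferon list passed (adjusted p 0.391). Rises and falls were 3 and 1 of 10 endocrine pancreas genes, 1 and 5 of 14 heart genes, 1 and 3 of 21 myeloid genes, 1 and 4 of 17 ionocyte genes, 1 and 4 of 17 bone genes, 4 and 2 of 25 endothelial genes, 3 and 2 of 17 pronephros genes and 1 and 1 of 13 mitochondrially encoded genes (adjusted p 0.103 to 0.863), and the bone list had an adjusted p of 0.0352 among genes with a mean FPKM of at least 5. Some of these balances depended on scaling, with rises and falls of 6 and 3 for myeloid, 3 and 3 for ionocyte and 2 and 1 for bone genes with library totals. With limma on quantile-normalized values, which changes the test as well as the scaling, they were 3 and 3 for endothelial and 2 and 0 for mitochondrially encoded genes. Of the lists that missed camera, fry called motile cilia, heat shock and endocrine pancreas as higher on balance (adjusted p 0.00826, 0.00826 and 0.0297). These calls are on the FPKM scale, where the median log2 change of all genes was 0.101. On the TMM scale the medians of these lists were 0.29, -0.08 and 0.08. The pituitary and thyroid list (4 genes, 1 rise) and the vitellogenin list (1 gene, not passing) were too short for camera.

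Called genes were not gathered on the chromosome of rhpn2 at this precision. On chromosome 7, 352 of 1017 genes (34.6%) changed, against 33.1% elsewhere (odds ratio 1.07, 95% interval 0.933 to 1.22, two-sided Fisher's exact p = 0.339). Within 10 Mb of rhpn2, 108 of 306 genes (35.3%) changed (odds ratio 1.1, 95% interval 0.859 to 1.40, Fisher's exact p = 0.463), and the odds ratio was 1.26 (p = 0.0452) when no filter on low counts was used. Genes are not independent replicates in these tests.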

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

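The scaling by library totals, camera on the counts and the combination of limma with other settings were chosen after the data were seen, and all other alternatives given here before. Counts of changed genes stayed within 1.5 times except under narrower definitions, where fewer genes could pass. A mean FPKM of at least 5 left 3861 changed genes, 1922 higher and 1939 lower, and an absolute log2 change of at least 1 left 1591, 637 higher and 954 lower. Genes lower numbered 2075 with limma on FPKM, 2039 and 2096 with pseudocounts of 0.1 and 5, and 2006 without trend, and limma used FPKM scaled by library totals. DESeq2 called 6065 genes. Leaving out a library gave 4886 (without mutant b) to 6710 (without wild type a). With the replicate letter as a block 5356 genes changed, 2669 higher and 2687 lower. Deviations of same-letter samples correlated at -0.116, -0.0486 and -0.162, and those of samples with different letters at -0.00318 to 0.148. No positive pairing by letter was seen. With so few samples per group, these values cannot decide whether the letters mark a shared clutch or collection day. The block also took the pigment list to an adjusted p of 0.0349 and ended the calls of rpl6, rpl30 and hmx2 (0.0539, 0.0843 and 0.0698). With an estimated correlation 0 lists passed. Quantile normalization reversed the ribosomal protein list (signed -log10 adjusted p 0.0706, adjusted p 0.85); the cause was not tested. With no filter on low counts the odds ratio within 10 Mb of rhpn2 was 1.26; the cause was not tested. Of 1684 alternative values for 86 named genes other than rhpn2, 1658 kept direction and side of the threshold, 26 in 5 genes (rpl6, rpl30, otofb, oc90 and hmx2) no longer passed and 0 reversed. For the lists, DESeq2, the robust fit and limma without trend were not run. The pseudocount makes changes of low genes smaller in limma (hbl3 -2.26 against -5.16). Depth limits genes near the floor, such as snoU2_19, fabp6 and hbl3.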

Other observations

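The Gene Ontology tests, the splits of the samples, the scaling tests, the clock arms, the place of large changes relative to rhpn2, their counts on and off chromosome 4 and the neighbouring pairs without those of 1 clone were chosen after the results were seen, while the early embryo list and the first count of neighbouring pairs were written before their values were looked up. Genes of Notch signaling, microtubule-based movement and axon guidance were enriched among those higher in mutants. Of 44 tested genes of the Notch signaling pathway 19 rose (adjusted p 0.00749), with the ligand genes dlb, dld and dla at log2 changes of 0.99, 1.01 and 0.87 and the target gene her12 at 1.59. Of 66 genes of microtubule-based movement 28 rose (adjusted p 0.00033), among them the kinesin genes KIF2A (0.88), cenpe (0.68) and kif2c (0.78), and of 76 axon guidance genes 27 rose (adjusted p 0.00749). Of 15 genes of the positive regulation of neuron differentiation 9 rose (adjusted p 0.0168, and 0.056 with library totals), among them neurog1, ascl1b and ascl1a at 1.32, 0.97 and 0.92. The fixed neuron and glia lists did not pass camera.

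Genes of glycolysis, fatty acid biosynthesis and the response to oxidative stress were enriched among the lower genes. Of 34 genes of the glycolytic process 18 fell (adjusted p 0.000294), with pfkma at -0.69, pkmb at -0.74 and eno1b at -1.05. Of 36 genes of fatty acid biosynthesis 18 fell (adjusted p 0.00065), including elovl1a (-1.28), elovl4b (-1.20) and elovl2 (-1.85), and of 32 genes of the response to oxidative stress 15 fell (adjusted p 0.00639), with gpx3 at -2.33 and nfe2l2a at -0.80. Among 726 terms tested, 14 passed for higher and 14 for lower genes, of which 10 and 13 also passed with library totals. With all 13214 annotated genes as background, 18 and 10 passed. Terms share genes, and these tests treat genes as independent, so their p-values are too small where genes move together.

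The first pattern is the lower eye, digestive, liver and cartilage lists beside the higher cell cycle list. A factor per library moves all genes alike and cannot part these lists from the rest, so quantile normalization was the scaling that could test this, and it argues against scaling as the whole source: the highest of the 6 lowered list medians, relative to the median of all genes, was then -0.375 and the cell cycle median 0.277, and all 7 lists passed camera at the preset correlation. An earlier developmental stage of the mutant samples may account for it and was tested with an early embryo list. Of its 18 genes 4 rose, including igf2bp3 and hmga2 (adjusted p 0.0507 without mutant b), and 2 fell, with a median of 0.19 and a camera p of 0.171, which leaves the stage open. Loss of rhpn2 itself, slower growth caused by it and a stage difference between clutches cannot be told apart here, because the labels give the same 72 hours for both groups and no clutch.

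The second pattern is the lower clock list. Quantile normalization, the scaling that could move it relative to all genes, left its median at -1.03 and its call by camera at that correlation, which argues against scaling as the whole source. A different clock phase at collection could lower genes of 1 arm and raise those of the other. The set taken as the negative arm also held tef, dbp and hlf genes, and that taken as the positive arm also held nfil3 genes. The negative set had a median of -1.18 over 22 genes, with 19 falls and 1 rise. The positive set had a median of -0.34 over 13 genes, with 7 falls and 1 rise. In the positive set arntl2 rose, and clocka, clockb and arntl1a did not pass. Its falls were npas2 and arntl1b, by 1.12 and 0.51 on the log2 scale, and ror and nfil3 genes. At the preset correlation camera placed both sets lower, with p = 3.27e-16 for the negative and 0.0112 for the positive set. With an estimated correlation the camera p was 0.0282 for the negative and 0.301 for the positive set. Both medians were negative, so the opposite movement that antiphase arms would show was not seen in the medians of these mixed sets. Arms that are not in exact antiphase can also both be low at 1 time of day, so the phase stays open. Time of day, light and genotype cannot be told apart, since the labels give no time of collection.

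The third pattern is the 300 genes other than rhpn2 that changed at least 4-fold, 82 higher and 218 lower. A haplotype linked to rhpn2 is argued against as the main source, because 2.67% of them (8 genes) lie within 10 Mb of rhpn2. That window held 306 genes other than rhpn2, of 20032 tested, and an excess there at this size of change was not tested. Haplotype differences elsewhere between the stocks may contribute: 27 neighbouring pairs without a shared gene family stem both changed this much, or 23 without pairs named after 1 clone, against a median of 5 and a maximum of 17 in 10000 shuffles of the latter within chromosomes (permutation p = 1e-04, the smallest they can give), and 19 of the 23 moved in the same direction. On chromosome 4, 43 of 836 genes (5.14%) changed this much against 1.34% elsewhere (95% interval of the odds ratio 2.8 to 5.58, Fisher's exact p = 1.44e-12), and without that chromosome there were 12 pairs against a median of 4 and a maximum of 12 (permutation p = 3e-04). Only 3 pairs have symbols that are not clone-based on both sides, among them scg5 and ACTC1 (1 of many), so unrecognized tandem copies, shared reads and neighbours regulated together stay open.

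The real split of the 6 samples called 6654 genes, and the highest of the 9 others called 0 with edgeR, with up to 526 genes at an unadjusted p below 0.05. Each of the 9 others mixes wild type and mutant samples, so the difference between the groups adds to the spread within their sets. Few calls follow from that alone, and the 0 is not a measure of false calls. Only 1 of the 10 splits gave as many genes, and 10 splits are too few for a share below 0.05.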
